A study of Mus musculus with 7 samples.

How the data were processed

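mRNA sequencing was analysed for 7 tumour libraries, 4 from untreated model mice and 3 from mice given high-dose Ze-qi decoction (ZQD). Per the labels' protocols, LLC cells were injected under the skin of 6-week-old mice, treatment groups were assigned after 3 days, and poly(A) RNA was made into paired-end libraries with a kit whose strandedness is not given in the sources used here. The labels name a pair of sequencing platforms without saying which served which library, and give no batch. Groups were taken from the sample titles and the treatment label.

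The authors deposited FPKM for all 7 libraries and raw counts per gene for control 1 and control 2. Per the submitters' processing notes, the tools were HISAT2, featureCounts, Subread and DESeq2. Their versions, roles, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. In the 2 count files, the deposited FPKM equal the count divided by gene length and by the total count. That relation gave a length for 27421 of 32212 genes, and with it reads were rebuilt from the FPKM of all 7 libraries. Where both count files gave a length (22260 genes), the lengths differed by at most 4.81e-07 of their value. In the 5 libraries with no count file, all (100%) of the rebuilt values lay within 0.05 reads of a whole number; in control 1 and control 2 the rebuilt reads follow from the lengths by construction. No length could be had for 4791 genes, of which 6 passed the expression filter; these 6 are left out of the read-based tests. Symbols came from a gene name table and matched 31571 (98.0%) of the gene identifiers. Where 2 identifiers shared a symbol, a list took the one of higher mean FPKM.

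The total count per library, as the FPKM steps give it, was 49914395, 38866505, 32065288 and 39391002 reads for controls 1 to 4 and 36867523, 38673663 and 34765330 reads for ZQD 1 to 3. One read was worth 0.020 to 0.031 FPKM in a gene of 1 kb, and 3 reads, the limit that a count of 0 allows, 0.060 to 0.094. These limits cover counting error only, since reads without molecular identifiers are not independent molecules. FPKM are shares of each library, so a larger share for mitochondrially encoded genes lowers the values of the rest.

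The main test used limma 3.58.1 (linear model with empirical Bayes moderation and trend) in R 4.3.3 on log2(FPKM + 0.5), for 14838 genes with an FPKM of at least 0.5 in at least 3 libraries, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The 35 gene lists were fixed before the data were examined, and 32 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01. For each list and library, the mean of log2(FPKM + 0.5) over members was compared between groups by a two-sided exact permutation test over all 35 splits, whose smallest p is 0.0286. Members adjusted over the list alone are counted beside those adjusted over all genes. As alternatives, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the rebuilt reads of 14832 genes. DESeq2 gave no adjusted p for 2307 genes, which stay out of its calls. Other alternatives were the pseudocount, the filter, the scaling (TPM scale, median of ratios, TMM), library weights, no trend, the replicate number as a block, the correlation in camera, median list scores and each library left out in turn. A scaling without mitochondrially encoded genes was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

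The genes named were set by a rule fixed before the data were examined. It takes genes past the threshold whose groups do not overlap. Because fewer than 5 passed in either direction, it takes the 10 of smallest unadjusted p per direction with a mean FPKM of at least 1 in a group, leaving out predicted genes and receptor segments. From each list that passed it takes the 4 members of smallest p and from every other list the 2 most abundant members. It adds Padi4, Mpo, Elane, Cxcr2, S100a8, S100a9, Ly6g, Cxcl1, Cxcl2 and Mki67. Genes drawn in the plot of NET and neutrophil genes come from that set.

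The tests were run first on simulated reads with the libraries' means and depths, with 100 genes changed at each fold size. The changed genes were drawn only from those with more than 100 expected reads, so recovery of genes with fewer reads was not measured. Over 14832 genes simulated for ZQD against control, limma recovered 74% of genes changed by a log2 of 1 and 97% of those changed by 2, and called 10 of 14614 unchanged genes. edgeR recovered 81% and 100% with 14 unchanged genes called, and DESeq2 90% and 100% with 36. camera found the 1 shifted list and called 0 others. Each gene was simulated independently, so this does not show how often camera calls lists whose members vary together. For the trend checks, GC content was that of each gene's longest GENCODE transcript and length the one rebuilt from the FPKM, and both were had for 14677 (98.9%) of the tested genes.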

Results

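Gene expression was measured by mRNA sequencing in bulk subcutaneous tumours of C57BL/6J mice, grown from Lewis lung carcinoma (LLC) cells, a transplantable mouse lung cancer line. The 7 libraries comprised 4 from untreated model mice (control) and 3 from mice given a high dose of Ze-qi decoction (ZQD), a herbal preparation, at 42.67 g/kg. The labels number the samples within each group but do not say that each came from a separate mouse, so p-values measure only the spread between these samples, which may be technical. Tumours were taken at day 21 or day 22, both of which the labels give. The libraries held 32065288 to 49914395 counted reads in controls and 34765330 to 38673663 in ZQD, so the totals overlapped between groups (two-sided exact permutation p = 0.543). Values are FPKM (counted reads scaled by gene length and by the library's total), given as mean ± SD over 4 control and 3 ZQD libraries, and values joined by "against" are control against ZQD, with no change implied. Fold changes are ZQD minus control on the log2(FPKM + 0.5) scale, which understates changes of low genes.

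The comparison of ZQD with control tumours asks how the decoction changes gene expression in the tumour, and the series title names neutrophil extracellular traps (NETs), webs of DNA and granule proteins released by neutrophils, as its subject. In the ZQD tumours, interferon-stimulated, hypoxia and glycolysis, and heat shock and immediate early genes were lower than in controls, with mean log2 fold changes of -0.80, -0.53 and -0.37. Mitochondrially encoded transcripts (0.58) and markers of neutrophils (0.67), macrophages (0.47) and T cells (0.27) were higher. The NET formation list was also higher (0.27), tested without the granule enzyme genes Mpo and Elane. These 8 lists passed in camera at a preset correlation, and each lost its call with an estimated one (adjusted p = 0.414), while the neutrophil value was 0.29 without ZQD 2 and the T cell value 0.15 without control 4. Padi4, which encodes the histone citrullinating enzyme of NET formation, was at 12.8 ± 1.34 FPKM in controls and 12.1 ± 1.41 in ZQD (log2 fold change -0.081, and -0.15 to 0.012 with 1 library left out). In ZQD 2, Padi4 was at 12.4 FPKM, within the range of controls, although S100a8, S100a9 and Cxcr2 were highest there. The Padi4 transcript thus did not follow those neutrophil genes, and its level is no measure of NETs. No single gene passed the adjusted threshold in the limma test of 14838 genes: 0 genes had a Benjamini-Hochberg adjusted p under 0.05, the smallest being 0.078, while 2306 had an unadjusted p under 0.05 where chance gives about 742. Of those 2306 genes, 773 were higher and 1533 lower in ZQD, a split that moved with the scaling. Median-of-ratios factors gave 1097 higher and 1082 lower, TMM 1113 and 1071, and scaling without mitochondrially encoded genes 1030 and 1113. The TPM scale gave 379 higher and 2856 lower, with a median log2 fold change over all genes of -0.13 in place of -0.043. edgeR on reads rebuilt from the FPKM also called 0 genes (2221 at an unadjusted p under 0.05), whereas DESeq2 on the same reads called 517, of which 288 were higher and 229 lower.

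The 10 lower genes of smallest p in which all ZQD libraries lay below all controls began with Cx3cl1 (ENSMUSG00000031778), the chemokine fractalkine. It was at 10.02 ± 0.488 FPKM in controls and 5.40 ± 0.274 in ZQD, a log2 fold change of -0.84 (SE 0.083, limma adjusted p = 0.078). P4ha2 (ENSMUSG00000018906) and P4ha1 (ENSMUSG00000019916), subunits of the collagen prolyl 4-hydroxylase, were lower as well. P4ha2 was at 29.8 ± 0.567 against 19.2 ± 1.26 FPKM (log2 fold change -0.62) and P4ha1 at 81.1 ± 7.43 against 50.5 ± 6.13 (-0.68). Irs1, an adaptor of the insulin receptor, was at 3.89 ± 0.193 against 2.23 ± 0.238 FPKM, and Agrn, which encodes agrin, at 21.2 ± 2.42 against 12.98 ± 0.699. The others were Pigyl (log2 fold change -0.65), AI837181 (-0.52), Slc9a8 (-0.54), a second identifier that bears the symbol Aldoa (ENSMUSG00000114515, -0.93), and Mir7671, which had 4, 2, 5 and 2 reads in the controls and 0 in each ZQD library. None of these 10 passed in limma.

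Among the 10 higher genes chosen the same way, Gimap4 (ENSMUSG00000054435), a GTPase of lymphocytes, was at 13.4 ± 1.62 FPKM in controls and 24.9 ± 1.91 in ZQD, a log2 fold change of 0.87 (SE 0.109, limma adjusted p = 0.113). Gbp2b (ENSMUSG00000040264), a guanylate-binding protein, was at 1.37 ± 0.138 against 4.93 ± 1.78 FPKM (log2 fold change 1.49). Ncf1 (ENSMUSG00000015950), a cytosolic subunit of the phagocyte NADPH oxidase, was at 8.08 ± 1.21 against 14.5 ± 1.23 FPKM (0.82). Cbfb, a partner of RUNX transcription factors, was at 66.9 ± 5.73 FPKM in controls and 102.2 ± 7.91 in ZQD. Rpl21 (61.7 ± 11.2 against 128.1 ± 10.5 FPKM) and its pseudogene Rpl21-ps8 (5.22 ± 0.641 against 10.3 ± 0.534 FPKM) are near-identical copies, so their values are uncertain, as are those of Gbp2b within its gene family. The remaining genes were Hpgd (log2 fold change 1.22), Cox6c2 (1.12), Serpina3f (0.71) and Spink2 (0.64), and none of the 10 passed in limma. Hpgd lay below the filter of 0.5 FPKM in every control, so it could enter the test only with groups that do not overlap. Cox6c2 had few reads, with 14, 8, 11 and 11 in the controls and 23, 26 and 32 in ZQD. Across both directions, limma adjusted p ran from 0.078 to 0.131, and 16 of the 20 genes passed in DESeq2, which gave no adjusted p for the other 4. In all, 2254 genes (15.19%) had groups that did not overlap, where chance gives 5.71%.

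**Figure D1:**
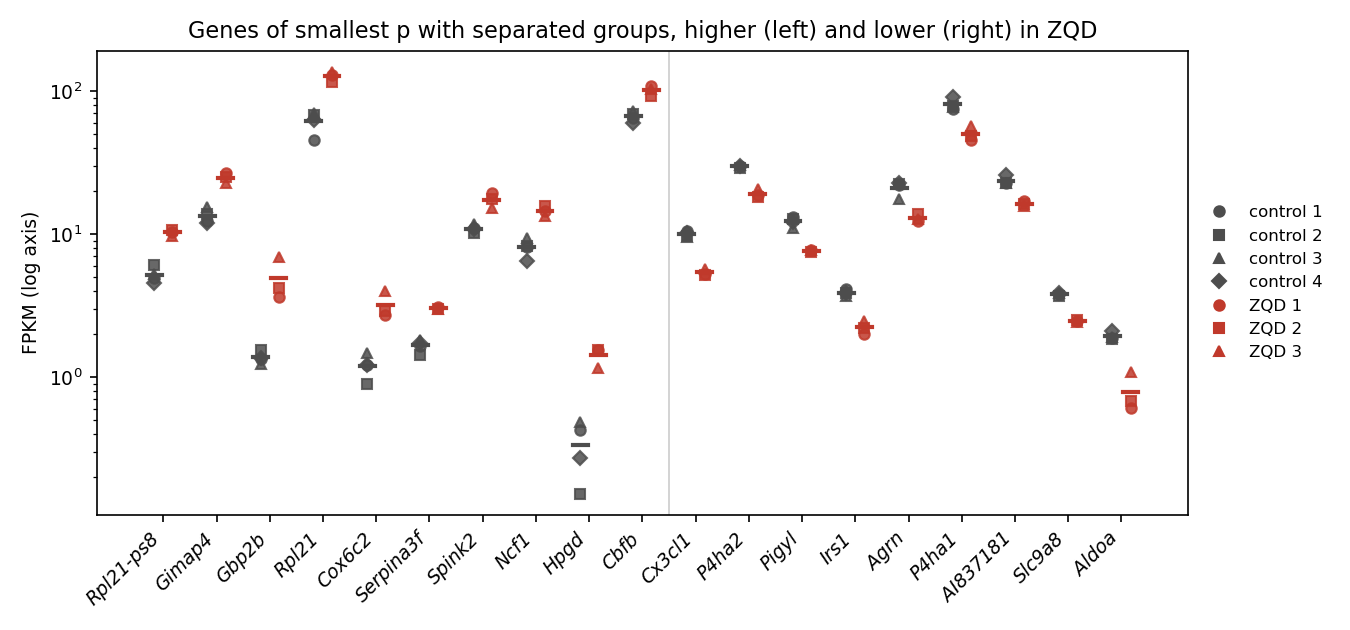
FPKM on a log axis of the genes of smallest p whose groups do not overlap, 10 higher (left of the line) and 9 lower (right) in ZQD; each point is 1 library, bars are group means over 4 control and 3 ZQD libraries, and Mir7671 is not drawn because it is at 0 in ZQD. Cx3cl1 lies near 10.02 in controls and 5.40 in ZQD, and none of these genes passed the adjusted threshold in limma; the symbol Aldoa stands for ENSMUSG00000114515.

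The NET formation list holds genes of neutrophil granule enzymes, the phagocyte oxidase and surface receptors that trigger the process. Of its 25 genes 21 were measured, and the granule enzyme genes Mpo and Elane were among those that were not. Of 21 measured members, 16 were higher and 5 lower in ZQD (camera adjusted p = 3.56e-05; adjusted p = 0.414 with an estimated correlation). In limma, 4 members passed when adjusted over the list alone, and 0 passed over all genes. The 4 were Ncf1 (above), Fcgr3, an activating IgG receptor (47.6 ± 7.59 against 81.3 ± 13.2 FPKM), Itgam, the integrin CD11b (8.51 ± 2.05 against 15.3 ± 2.89 FPKM), and the receptor Tlr2 (8.21 ± 1.47 against 12.97 ± 2.42 FPKM). DESeq2 over all genes called each of them (adjusted p = 2.81e-06, 0.000315, 0.00223 and 0.00723). edgeR on the same reads called none of them (adjusted p = 0.0994, 0.123, 0.135 and 0.147). Both tests use the libraries from which these genes were picked, so neither is independent support. These 4 genes are also expressed by macrophages, whose markers were higher in the same libraries. The list score, a library's mean log2(FPKM + 0.5) over members, was 3.88 ± 0.10 (SD, n = 4) in controls and 4.15 ± 0.08 (SD, n = 3) in ZQD (exact permutation p = 0.0571). The granule enzyme genes Mpo and Elane had at most 4 reads in any library and were not tested.

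Neutrophil markers were higher for 14 of 15 measured members (camera adjusted p = 2.47e-06; adjusted p = 0.414 with an estimated correlation), and 2 passed over the list alone. These were Lcn2, lipocalin 2 (0.278 ± 0.088 against 0.926 ± 0.296 FPKM), and G0s2 (0.880 ± 0.330 against 2.62 ± 1.11 FPKM). Lcn2 lay below the filter of 0.5 FPKM in every control and entered the test only through the ZQD libraries. Clec4e had a log2 fold change of 0.93 and Stfa2l1 of 1.41 (0.44 and 0.75 without ZQD 2). S100a8 and S100a9, the calprotectin subunits abundant in neutrophils, were at 1.90 ± 0.940 and 10.9 ± 5.10 FPKM in controls and at 4.42 ± 3.17 and 26.4 ± 20.1 in ZQD. The chemokine receptor Cxcr2 was at 0.410 ± 0.158 and 1.002 ± 0.9903 FPKM. The log2 fold changes of S100a8, S100a9 and Cxcr2 were 0.90, 1.06 and 0.54, and without ZQD 2 they were 0.41, 0.48 and 0.042 (1.38, 1.63 and 0.88 without ZQD 1). In ZQD 1, G0s2 was at its highest (3.39 FPKM) and Lcn2 was above all controls (0.962). S100a8 (1.68), S100a9 (9.56) and Cxcr2 (0.320) lay within the range of controls in that library. Lcn2 and G0s2 thus did not follow these neutrophil genes there, and their cell of origin was not tested. Ly6g had at most 9 reads in any library and was not tested. The score was 1.34 ± 0.33 (SD, n = 4) in controls and 2.01 ± 0.66 (SD, n = 3) in ZQD (exact permutation p = 0.114). Without ZQD 2, the mean log2 fold change was 0.29 in place of 0.67 (camera adjusted p = 0.00431). Platelet and erythroid genes, which mark blood, were highest in that same library, with a score of 5.22 against 2.54 to 4.03 in the others.

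Among neutrophil recruiting and activating cytokines, 11 of 16 were higher (mean log2 fold change 0.30, camera adjusted p = 0.111). The neutrophil chemoattractants Cxcl1 and Cxcl2 were at 23.3 ± 14.1 and 3.82 ± 1.40 FPKM in controls and at 15.7 ± 4.50 and 12.2 ± 12.9 in ZQD. Csf1, the macrophage growth factor, was at 95.1 ± 21.9 FPKM in controls and 69.0 ± 15.4 in ZQD, and Ptgs2, cyclooxygenase 2, at 27.2 ± 5.52 and 24.8 ± 16.5. None of these 4 passed in limma. The log2 fold change of Cxcl2 was 1.06, with 0.23 without ZQD 2 and 1.79 without ZQD 1. That of Cxcl1 was -0.37, with -0.021 without control 1, -0.81 without control 4 and -0.12 without ZQD 1. Without ZQD 1, Csf1 was at -0.30 in place of -0.46 and Ptgs2 at 0.13 in place of -0.31 (-0.81 without ZQD 2). The list's mean log2 fold change was 0.63 without ZQD 1 (camera adjusted p = 0.000198), 0.16 without control 4 (0.466) and -0.11 without ZQD 2 (0.426, test direction down).

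**Figure D2:**
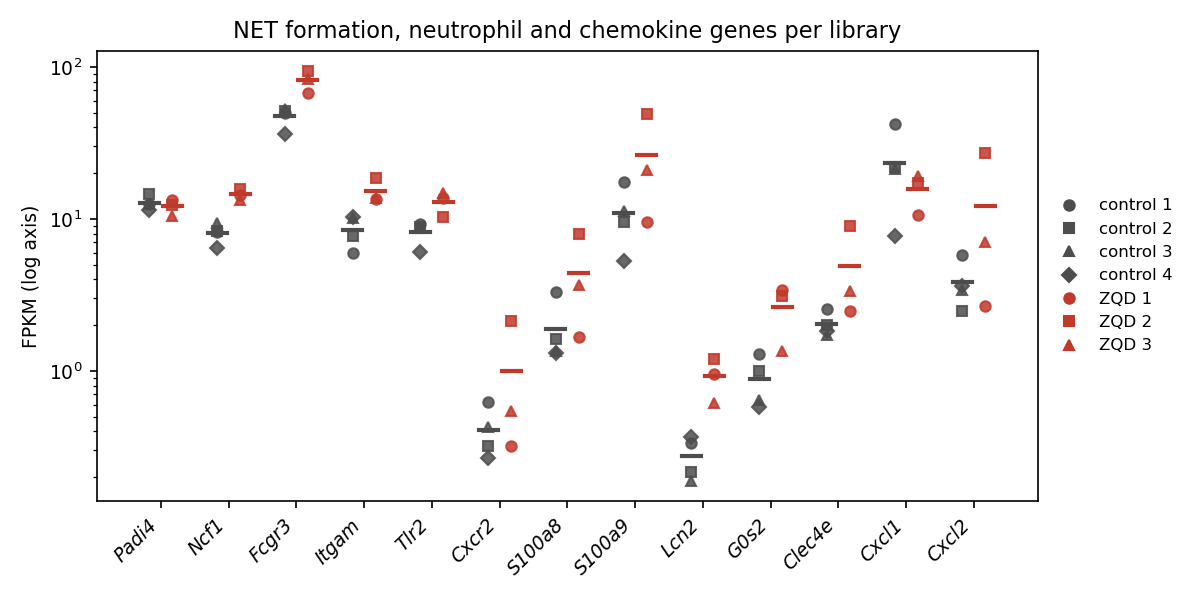
FPKM on a log axis of 13 NET formation, neutrophil and chemokine genes; each point is 1 library and bars are group means over 4 control and 3 ZQD libraries. Padi4 overlaps between the groups, Ncf1, Fcgr3, Itgam, Tlr2, Lcn2 and G0s2 have all ZQD libraries above all controls, and ZQD 2 is the highest library for Cxcr2, S100a8, S100a9, Clec4e and Cxcl2.

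Interferon-stimulated genes, the antiviral effectors induced by type I interferon, were lower for all 23 members (camera adjusted p = 3.48e-14; adjusted p = 0.414 with an estimated correlation). In limma, 22 passed when adjusted over the list alone, and 0 passed over all genes. Ifit3 (ENSMUSG00000074896) was at 82.2 ± 27.8 FPKM in controls and 32.1 ± 8.65 in ZQD. The 2'-5' oligoadenylate synthetases Oas2 and Oas1a were at 28.9 ± 5.17 against 15.7 ± 3.64 and at 23.1 ± 6.09 against 11.7 ± 1.90 FPKM. The ISG15 protease Usp18 was at 15.3 ± 4.62 against 6.89 ± 1.92. The score was 5.10 ± 0.36 (SD, n = 4) in controls and 4.29 ± 0.25 (SD, n = 3) in ZQD, with all ZQD libraries below all controls (exact permutation p = 0.0286, the smallest the design allows). The interferon gamma response and antigen presentation list did not pass: 11 of 28 members were higher and 17 lower, with a mean log2 fold change of 0.018, a median of -0.034 and a test direction of down (camera adjusted p = 0.906). Its most abundant members were B2m, the MHC class I light chain (4819 ± 292.3 FPKM in controls and 4969 ± 888.1 in ZQD), and H2-D1, a heavy chain (621.8 ± 51.5 and 490.2 ± 28.6).

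Hypoxia and glycolysis genes were lower for all 22 measured members (mean log2 fold change -0.53, camera adjusted p = 3.82e-08; adjusted p = 0.414 with an estimated correlation), 7 of them past the threshold over the list alone. The oxygen-sensing prolyl hydroxylase Egln3 was at 64.8 ± 6.03 FPKM in controls and 44.1 ± 3.11 in ZQD. Hexokinase Hk2 was at 39.4 ± 6.28 against 21.5 ± 5.87 FPKM and the phosphofructokinase Pfkl at 35.3 ± 4.47 against 23.5 ± 3.51, with P4ha1 as above. The score was 5.63 ± 0.23 (SD, n = 4) in controls and 5.10 ± 0.31 (SD, n = 3) in ZQD (exact permutation p = 0.0286). Mitochondrially encoded genes of the respiratory chain were higher for 13 of 13 members (mean log2 fold change 0.58, camera adjusted p = 4.8e-09; adjusted p = 0.414 with an estimated correlation), 8 past the threshold over the list alone. mt-Nd1 was at 10590 ± 2413 against 19070 ± 3144 FPKM and mt-Nd4 at 1914 ± 381.5 against 2912 ± 163.1. mt-Nd6 was at 908.2 ± 191.1 against 1655 ± 500.6. mt-Atp6 was at 63.8 ± 5.75 against 104.0 ± 28.5. The score was 8.91 ± 0.26 (SD, n = 4) in controls and 9.48 ± 0.20 (SD, n = 3) in ZQD (exact permutation p = 0.0571). Their share of reads was 6.72% ± 1.19 (SD, n = 4) in controls and 10.2% ± 1.23 (SD, n = 3) in ZQD (exact permutation p = 0.0286), so it differed between the same libraries as each gene group compared here. Nuclear genes of oxidative phosphorylation did not pass, with 14 of 24 higher (camera adjusted p = 0.554, mean log2 fold change -0.0071, median 0.020). Atp5a1 and Atp5b, subunits of the ATP synthase, were at 242.1 ± 20.3 and 181.3 ± 27.0 FPKM in controls and 252.4 ± 7.05 and 154.5 ± 4.41 in ZQD (Atp5b log2 fold change -0.22, and -0.12 without control 4).

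Heat shock and immediate early genes, which respond within minutes to stress or stimulation, were lower for 14 of 16 members (camera adjusted p = 0.000348; adjusted p = 0.414 with an estimated correlation), 7 past the threshold over the list alone. The chaperones Hspb1 (32.5 ± 6.20 against 17.2 ± 3.15 FPKM), Hspa1b (28.7 ± 5.12 against 16.2 ± 2.88) and Hspa1a (2.96 ± 0.669 against 1.79 ± 0.388) and the transcription factor Junb (52.1 ± 9.93 against 30.7 ± 3.34) had all ZQD libraries below all controls. Hspa1a and Hspa1b are near-identical copies, so their division of reads is uncertain. The score was 4.15 ± 0.16 (SD, n = 4) in controls and 3.78 ± 0.18 (SD, n = 3) in ZQD (exact permutation p = 0.0286). Cytosolic ribosomal protein genes were lower for 24 of 27 members (mean log2 fold change -0.22, camera adjusted p = 6.4e-05; adjusted p = 0.568 with an estimated correlation), 7 past the threshold over the list alone. Rps14 was at 82.9 ± 14.4 against 54.3 ± 1.83 FPKM, and Rpl18, Rpl15 and Rps18 had log2 fold changes of -0.42, -0.35 and -0.39. Unfolded protein response genes were lower for 15 of 19 members (mean log2 fold change -0.21, camera adjusted p = 0.0492; adjusted p = 0.568 with an estimated correlation), 0 past the threshold over the list alone. The chaperone Hspa5 was at 282.6 ± 17.6 FPKM in controls and 238.5 ± 19.2 in ZQD, and Sdf2l1, Chac1 and Atf4 had log2 fold changes of -0.47, -0.72 and -0.44 (Chac1 -0.43 and Atf4 -0.22 without ZQD 1). That call was lost without control 2 (adjusted p = 0.148), control 3 (0.0556), control 4 (0.116) or ZQD 2 (0.288), and with median-of-ratios scaling (0.0706).

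Markers of other immune cells were mostly higher. Macrophage and monocyte markers were higher for 18 of 20 members (mean log2 fold change 0.47, camera adjusted p = 2.55e-06; adjusted p = 0.414 with an estimated correlation), 1 past the threshold over the list alone. Folr2, the folate receptor of resident macrophages, was at 2.14 ± 0.525 against 7.01 ± 4.14 FPKM and the mannose receptor Mrc1 at 8.11 ± 2.82 against 25.03 ± 19.5. The chemokine receptor Ccr2 was at 3.96 ± 1.79 against 7.70 ± 2.21 and Cd14 at 11.6 ± 2.51 against 18.6 ± 5.87. Without ZQD 2, the log2 fold changes of Mrc1 and Cd14 were 0.79 and 0.41 in place of 1.38 and 0.64. T cell markers were higher for 19 of 19 members (mean log2 fold change 0.27, camera adjusted p = 1.24e-05; adjusted p = 0.414 with an estimated correlation), 0 past the threshold over the list alone. Trbc1, a constant segment of the T cell receptor, was at 2.14 ± 0.150 against 2.93 ± 0.280 FPKM, and Icos, Tcf7 and Thy1 had log2 fold changes of 0.54, 0.43 and 0.46 (Thy1 0.27 without ZQD 2). The mean was 0.15 without control 4. NK and cytotoxic effector genes were higher for 11 of 13 (mean 0.24, camera adjusted p = 0.00275; adjusted p = 0.414 with an estimated correlation). The NK receptors Klrd1 (4.84 ± 1.06 against 7.44 ± 0.317 FPKM) and Klrk1 (0.785 ± 0.203 against 1.53 ± 0.411), Eomes (log2 fold change 0.48, and 0.32 without control 1) and Fasl (0.24) had the smallest unadjusted p, with 0 past the threshold over the list alone. Their call was lost in genes with a mean FPKM of at least 2 (adjusted p = 0.087). Immune checkpoint genes were higher for 11 of 14 (mean 0.21, camera adjusted p = 0.00292; adjusted p = 0.414 with an estimated correlation), 2 past the threshold over the list alone. Havcr2, which encodes TIM-3, was at 11.8 ± 1.97 against 17.7 ± 2.25 FPKM and Entpd1, which encodes CD39, at 7.33 ± 1.21 against 11.1 ± 1.78, with log2 fold changes of 0.52 for Cd80 (0.34 without control 4) and 0.47 for Pdcd1.

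Mast cell and basophil markers were higher for 6 of 7 (mean log2 fold change 0.80, camera adjusted p = 0.0286; adjusted p = 0.568 with an estimated correlation), with 0 past the threshold over the list alone. Mast cell and basophil scores overlapped between the groups (exact permutation p = 0.257). The mast cell protease Cpa3 was at 2.76 ± 1.98 FPKM in controls and 13.4 ± 10.3 in ZQD, and Cma1, Mcpt4 and Tpsb2 had log2 fold changes of 1.41, 1.32 and 0.82. For Cpa3 (1.69), Cma1, Mcpt4 and Tpsb2 these were 1.10, 0.71, 0.64 and 0.24 without ZQD 2 and 2.76, 2.51, 2.46 and 1.81 without ZQD 3. Mcpt4 and Tpsb2 were at 0.85 and 0.40 without ZQD 1, and Tpsb2 at 1.23 without control 1. This call was lost without control 2 (adjusted p = 0.0703), control 3 (0.0895), control 4 (0.0648) or ZQD 2 (0.37, mean 0.37), and without ZQD 3 the mean was 1.46. It was also lost with median-of-ratios scaling (adjusted p = 0.0674). B and plasma cell markers (5 of 6 higher, camera adjusted p = 0.37) and dendritic cell markers (4 of 11 higher, mean log2 fold change 0.014, median -0.058, adjusted p = 0.906, test direction up and with median-of-ratios scaling down) did not pass. The immunoglobulin genes Igkc and Ighm were at 11.2 ± 7.74 and 14.1 ± 6.63 FPKM in controls and 22.1 ± 15.6 and 14.7 ± 3.89 in ZQD. The log2 fold change of Igkc was 0.95 (0.42 without ZQD 1) and that of Ighm 0.15 (-0.16 to 0.38 with 1 library left out). Fscn1, which encodes fascin, was at 57.8 ± 10.4 against 40.0 ± 2.93 FPKM and Itgax, the integrin CD11c, was at 25.7 ± 6.00 and 16.1 ± 6.74, with overlapping groups and a log2 fold change of -0.72 (-0.35 without ZQD 2). Neither passed in limma.

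Adipocyte genes were higher for 8 of 8 measured members (mean log2 fold change 0.91, camera adjusted p = 0.000369; adjusted p = 0.414 with an estimated correlation), 0 past the threshold over the list alone. Adipocyte scores overlapped between the groups (exact permutation p = 0.143). Lpl, lipoprotein lipase, was at 3.06 ± 0.834 against 4.96 ± 0.544 FPKM and Fabp4 at 3.67 ± 1.32 against 13.6 ± 12.7, with log2 fold changes of 0.24 for Pnpla2 and 0.33 for Lipe. Without ZQD 1, Fabp4 (1.28), Pnpla2 and Lipe were at 0.52, 0.15 and 0.15, and without ZQD 3 Fabp4 was at 2.16. The mean was 0.36 without ZQD 1 and 1.42 without ZQD 3. Lymphatic and pericyte markers were higher for 6 of 6 (mean 0.56, camera adjusted p = 0.0126; adjusted p = 0.514 with an estimated correlation), 0 past the threshold over the list alone. Lymphatic and pericyte scores overlapped between the groups (exact permutation p = 0.143). Pdpn, podoplanin, was at 6.44 ± 1.503 FPKM in controls and 11.2 ± 6.68 in ZQD, and Lyve1, Rgs5 and Abcc9 had log2 fold changes of 1.04, 0.79 and 0.45. For Pdpn (0.64), Lyve1, Rgs5 and Abcc9 these were 0.21, 0.15, 0.48 and 0.20 without ZQD 2. Pdpn was at 0.97 without ZQD 1, Rgs5 at 0.39 without control 4 and Abcc9 at 0.76 without ZQD 3. Without ZQD 2 the call was lost (mean 0.17, adjusted p = 0.355), as it was with no filter on low values (0.0821). Proliferation genes were higher for 21 of 30 (mean 0.095, camera adjusted p = 0.00126; adjusted p = 0.678 with an estimated correlation), with 2 higher and 1 lower past the threshold over the list alone. Proliferation scores overlapped between the groups (exact permutation p = 0.457). Nusap1 and Bub1b, of the mitotic spindle and its checkpoint, were at 14.6 ± 1.36 against 21.0 ± 2.06 and at 25.1 ± 1.69 against 32.1 ± 1.62 FPKM. The cell cycle transcription factor E2f1 was at 15.04 ± 0.521 against 12.1 ± 0.884, and Cenpe at 17.5 ± 1.31 against 20.7 ± 2.03. Mki67, the proliferation antigen Ki-67, was at 57.3 ± 7.83 FPKM in controls and 69.1 ± 12.1 in ZQD (log2 fold change 0.26, and 0.13 without ZQD 3). The proliferation call was lost without control 1 (mean 0.025, adjusted p = 0.107) or ZQD 3 (0.041, 0.0527), and the mean was 0.15 without control 4 or ZQD 1.

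Stromal and other lists did not pass. Fibroblast and extracellular matrix genes were higher for 12 of 21 (mean log2 fold change 0.31, camera adjusted p = 0.37). Fn1, fibronectin, was at 673.2 ± 160.9 FPKM in controls and 438.3 ± 46.2 in ZQD and Sparc at 369.2 ± 38.9 and 369.9 ± 66.7. Without control 1 or ZQD 3 the list passed, with adjusted p of 0.0246 and 0.000283. Its test direction was down without ZQD 2 (mean -0.029, adjusted p = 0.85) or control 4 (0.040, 0.723). Endothelial and angiogenesis genes were higher for 9 of 16 (mean -0.015, median 0.0054, test direction up but down with median-of-ratios scaling, adjusted p = 0.901), and passed as higher without ZQD 1 (0.00999). The direction was down without control 1 (0.562), ZQD 2 (0.171) or ZQD 3 (0.89). Endoglin, Eng, was at 43.3 ± 3.23 against 32.3 ± 1.49 FPKM and Apln, apelin, was at 22.8 ± 9.30 and 17.01 ± 6.31, with overlapping groups and a log2 fold change of -0.42 (-0.080 without ZQD 1, -0.17 without control 4 and -0.64 without ZQD 3). Neither passed in limma. Platelet and erythroid genes were higher for 4 of 7 (mean 0.20, adjusted p = 0.422). The mean was 0.69 without ZQD 3 (0.0446) and -0.65 without ZQD 2 (0.0589, test direction down). The globin Hbb-bs was at 79.3 ± 43.1 and 80.3 ± 87.4 FPKM and Hba-a1 at 34.2 ± 18.4 and 43.6 ± 43.4. Epithelial-mesenchymal transition genes were lower for 10 of 13 (adjusted p = 0.554). Vimentin, Vim, was at 557.6 ± 106.7 and 508.3 ± 22.3 FPKM and Tgfbi at 74.0 ± 15.7 and 72.9 ± 14.6. For extracellular proteases (mean -0.025, test direction up, adjusted p = 0.573), the cathepsins Ctss and Ctsb were at 339.9 ± 69.2 and 258.6 ± 8.12 FPKM in controls and at 430.2 ± 13.9 and 255.3 ± 31.7 in ZQD (Ctss log2 fold change 0.36, and 0.21 without control 4). Skeletal muscle genes (adjusted p = 0.901) passed as higher without control 1 (0.0401), with a test direction of down without control 2 (0.922), control 3 (0.912) or ZQD 3 (0.783). They included Tpm1 and Eno3 with log2 fold changes of -0.17 and -0.051. Schwann and nerve genes (0.931) included Pmp22 and Prx with 0.41 and -0.23.

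Stress and signalling lists that did not pass were p53 targets and apoptosis genes (mean log2 fold change -0.0088, test direction up, camera adjusted p = 0.409; Mcl1 0.014, Ccng1 0.20), NF-kB and inflammasome genes (adjusted p = 0.37; Nfkbia 0.067, Rela -0.075) and complement and coagulation genes (0.334; C1ra -0.30, Serping1 0.60). C1ra was at -0.52 without ZQD 1, -0.20 without control 1 and -0.13 without ZQD 3, Serping1 at 0.32 without ZQD 1 and 1.06 without ZQD 3, and Ccng1 at 0.078 without ZQD 1, 0.12 without control 4 and 0.32 without ZQD 2. Rela was at -0.033 without ZQD 1, -0.028 without ZQD 2 and -0.16 without ZQD 3. The complement list passed as higher without ZQD 3 (0.0106) and had a test direction of down without ZQD 2 (mean 0.012, adjusted p = 0.754). The NRF2 and xenobiotic response list had an adjusted p of 0.554, passed as higher without ZQD 1 (0.0172) and passed as lower without ZQD 2 (0.0284). Its most abundant members were Hmox1, heme oxygenase 1 (188.5 ± 44.1 and 277.9 ± 226.0 FPKM), and G6pdx (55.0 ± 4.92 and 65.2 ± 8.54). Without ZQD 2 their log2 fold changes were -0.33 in place of 0.29 and 0.14 in place of 0.24, and Hmox1 was at 0.15 without control 2, 0.72 without ZQD 1 and 0.49 without ZQD 3. Lists with fewer than 5 measured members were not tested as sets. These were keratinocyte and skin genes (3 measured; Sbsn 0.13, Trp63 0.11), lung epithelial genes (2; Napsa 0.24, with 0.12 without ZQD 1 and 0.15 without control 4, and Ager 0.12) and X inactivation and Y-linked genes (3; Eif2s3y 0.63, Ddx3y 0.59).

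**Figure D3:**
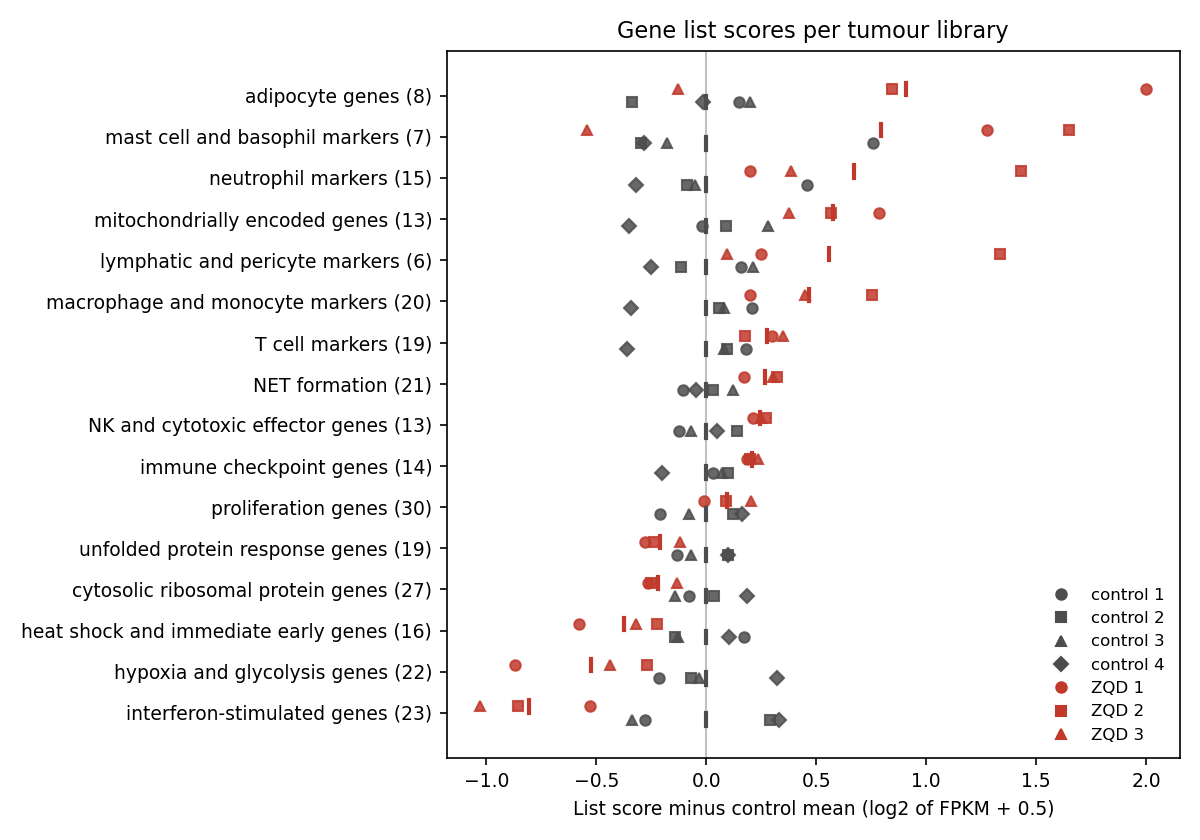
Scores of the 16 gene lists past the preset-correlation threshold, as a library's mean log2(FPKM + 0.5) over measured members (number in brackets) minus the control mean; each point is 1 library and bars are means over 4 control and 3 ZQD libraries. All 3 ZQD libraries lie below all 4 controls for interferon-stimulated, hypoxia and glycolysis, and heat shock and immediate early genes, and ZQD 2 is the highest library for neutrophil markers.

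Each gene list was fixed before the data were examined and tested against all other genes with camera at a preset inter-gene correlation of 0.01, and 16 of 32 lists passed (11 higher, 5 lower). With a correlation estimated per list 0 passed, 11 of the 35 ways to split the libraries into 4 and 3 gave at least 16 lists, and after adjustment over 35 lists the smallest exact p of a score was 0.25. Unadjusted, the exact permutation p of the score was 0.0857 for macrophage and monocyte markers, T cell markers, cytosolic ribosomal protein genes and unfolded protein response genes. It was 0.0571 for NK and cytotoxic effector genes and immune checkpoint genes. Taken as medians over members, the scores of interferon-stimulated, hypoxia and glycolysis, and heat shock genes had exact permutation p of 0.0571, 0.171 and 0.0571. The first principal component, with 28.77% of the variance, separated the groups (exact permutation p = 0.0286). Library pairs had Pearson r of 0.963 to 0.980 between groups, 0.975 to 0.984 within controls and 0.972 to 0.975 within ZQD, across genes, which are not independent replicates.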

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

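Of 166 values tested among the 4 controls, 19 had 1 control far from the other 3, where chance gives about 8.3, and none of these was tested further. Control 1 had a mast cell and basophil score of 1.90 against 0.847 to 0.965 in the other controls, with Cpa3 at 5.71 FPKM (1.56 to 2.08 in the others), Cma1 at 5.06 (1.42 to 1.72) and Tpsb2 at 5.37 (1.15 to 1.52). The same library had a skeletal muscle score of 3.33 (1.64 to 1.84) and S100a8 at 3.29 FPKM (1.32 to 1.63). Control 2 had a keratinocyte and skin score of 1.21 (0.489 to 0.599), Csf1 at 127.9 FPKM (83.2 to 85.6), Pdcd1 at 3.73 (2.05 to 2.31), Pnpla2 at 18.2 (20.4 to 20.8), Pmp22 at 15.4 (22.0 to 23.0) and Serping1 at 13.6 (23.2 to 24.9). Control 3 had Agrn at 17.6 FPKM (22.1 to 22.8) and Ager at 0.787 (0.529 to 0.569). Control 4 had AI837181 at 26.1 FPKM (22.7 to 23.0), Fcgr3 at 36.3 (50 to 52.5), Tlr2 at 6.03 (8.74 to 9.25), Entpd1 at 5.52 (7.86 to 8.00) and Prx at 1.70 (1.41 to 1.45). Control 4 was thus the lowest control for 3 genes that were higher in ZQD.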

How the results depend on the processing

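The scaling without mitochondrially encoded genes was chosen after seeing the data and the other alternatives before. limma called 0 genes in either direction with 0.1 or 1 as pseudocount, with no filter on low values, and under the TPM, median-of-ratios and TMM scalings. It also called 0 with library weights, without trend, with a fold limit, without mitochondrially encoded genes and with any 1 library left out. edgeR on rebuilt reads called 0. Genes with a mean FPKM of at least 2 gave 1 (0 higher, 1 lower), which is Cx3cl1 (adjusted p = 0.0398); the cause was not tested. An adjusted p under 0.10 gave 1. DESeq2 on rebuilt reads gave 517 (288 higher, 229 lower), 512 of them at an unadjusted limma p under 0.05, and it called 49 of the named genes. The cause of the gap to edgeR was not tested.

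With the replicate block, 1 gene passed, higher in ZQD: Marco, named here after its value was seen (log2 fold change 2.89, adjusted p = 0.0365). The numbers did not pair the samples: deviations from the group means correlated at 0.25 for control 1 with ZQD 1, 0.10 for the number 2 and -0.15 for the number 3, and not every sample correlated best with its own number.

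Of the 16 lists past the threshold at the preset correlation, 0 passed with an estimated correlation. In these 16 lists the estimate ran from 0.0295 for NK and cytotoxic effector genes to 0.81 for interferon-stimulated genes. It was above the preset value in each of them. The adjusted p then was 0.414 for neutrophil markers, NET formation, macrophage and monocyte markers, T cell markers, NK and cytotoxic effector genes, interferon-stimulated genes, immune checkpoint genes, adipocyte genes, hypoxia and glycolysis genes, heat shock and immediate early genes and mitochondrially encoded genes. It was 0.568 for mast cell and basophil markers, cytosolic ribosomal protein genes and unfolded protein response genes, 0.514 for lymphatic and pericyte markers and 0.678 for proliferation genes. With 1 library left out, 14 to 19 lists passed, and the adjusted p ran from 4.61e-10 to 0.00431 for neutrophil markers and from 7.04e-06 to 0.000442 for NET formation.

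In camera, by adjusted p, neutrophil recruiting and activating cytokines gained the call with TPM scale (0.0095). NK and cytotoxic effector genes lost the call with mean FPKM of at least 2 (0.087). Mast cell and basophil markers lost the call with median-of-ratios scaling (0.0674), TMM scaling (0.0709), arrayWeights (0.0621) and scaling without mitochondrially encoded genes (0.0583). Fibroblast and extracellular matrix genes gained the call with TPM scale (0.0472). Lymphatic and pericyte markers lost the call with no filter on low values (0.0821). Unfolded protein response genes lost the call with mean FPKM of at least 2 (0.087), median-of-ratios scaling (0.0706), TMM scaling (0.0717), arrayWeights (0.0803), no trend (0.0663), scaling without mitochondrially encoded genes (0.0583), edgeR on rebuilt reads (0.064) and DESeq2 on rebuilt reads (0.0779). The causes were not tested.

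Camera directions turned, with the adjusted p in brackets and none past the threshold, for dendritic cell markers with median-of-ratios scaling (0.951), TMM scaling (0.957), replicate block (0.842), scaling without mitochondrially encoded genes (0.988) and DESeq2 on rebuilt reads (0.996). They turned for platelet and erythroid genes with no filter on low values (0.944). They turned for interferon gamma response and antigen presentation with mean FPKM of at least 2 (0.981), TPM scale (0.987), arrayWeights (0.866) and replicate block (0.386). They turned for fibroblast and extracellular matrix genes with replicate block (0.656). They turned for endothelial and angiogenesis genes with mean FPKM of at least 2 (0.378), median-of-ratios scaling (0.951), TMM scaling (0.957), scaling without mitochondrially encoded genes (0.988) and edgeR on rebuilt reads (0.956). They turned for skeletal muscle genes with replicate block (0.968) and DESeq2 on rebuilt reads (0.657). They turned for Schwann and nerve genes with pseudocount 0.1 (0.991), TPM scale (0.798) and replicate block (0.936). They turned for extracellular protease genes with replicate block (0.957). The causes were not tested.

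With each library left out in turn, camera's adjusted p ran from 0.000198 to 0.466 for neutrophil recruiting and activating cytokines, 0.632 to 0.979 for dendritic cell markers, 6.73e-06 to 0.37 for mast cell and basophil markers, 0.0446 to 0.839 for platelet and erythroid genes, 0.176 to 0.817 for interferon gamma response and antigen presentation, 0.000283 to 0.85 for fibroblast and extracellular matrix genes and 0.00999 to 0.893 for endothelial and angiogenesis genes. It ran from 0.00163 to 0.355 for lymphatic and pericyte markers, 0.0401 to 0.98 for skeletal muscle genes, 0.64 to 0.898 for Schwann and nerve genes, 0.142 to 0.848 for extracellular protease genes, 4.03e-06 to 0.107 for proliferation genes, 0.0117 to 0.288 for unfolded protein response genes, 0.0172 to 0.899 for NRF2 and xenobiotic response genes and 0.0106 to 0.754 for complement and coagulation genes. Directions or calls turned in each of these 15 lists. Directions turned without control 2, control 4 or ZQD 1 for dendritic cell markers, without control 2, control 4, ZQD 2 or ZQD 3 for interferon gamma response and antigen presentation, without control 3, control 4 or ZQD 3 for Schwann and nerve genes and without ZQD 2 for extracellular protease genes. NRF2 and xenobiotic response genes passed as lower without ZQD 2 (0.0284) and as higher without ZQD 1 (0.0172), where fewer samples were used.

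Log2 fold changes of named genes, none called in either fit, turned sign for Hbb-bs with edgeR on rebuilt reads (0.083) and DESeq2 on rebuilt reads (0.086). They turned for Hba-a1 with TPM scale (-0.013) and arrayWeights (-0.064). They turned for B2m with TPM scale (-0.073). They turned for Sparc with median-of-ratios scaling (0.039), TMM scaling (0.042), scaling without mitochondrially encoded genes (0.037), edgeR on rebuilt reads (0.047) and DESeq2 on rebuilt reads (0.047). They turned for Eno3 with arrayWeights (0.041), replicate block (0.048), edgeR on rebuilt reads (0.037) and DESeq2 on rebuilt reads (0.038). They turned for Trp63 with replicate block (-0.18), edgeR on rebuilt reads (-0.055) and DESeq2 on rebuilt reads (-0.051). They turned for Vim with replicate block (0.0025). They turned for Tgfbi with median-of-ratios scaling (0.028), TMM scaling (0.031), scaling without mitochondrially encoded genes (0.026), edgeR on rebuilt reads (0.023) and DESeq2 on rebuilt reads (0.022). They turned for Ctsb with median-of-ratios scaling (0.020), TMM scaling (0.022), scaling without mitochondrially encoded genes (0.018), edgeR on rebuilt reads (0.028) and DESeq2 on rebuilt reads (0.029). They turned for Atp5a1 with TPM scale (-0.040). They turned for Mcl1 with TPM scale (-0.089), arrayWeights (-0.015) and replicate block (-0.024). They turned for Nfkbia with TPM scale (-0.036) and replicate block (-0.019). The causes were not tested.

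With each library left out in turn, log2 fold changes that turned sign ran from -0.81 to 0.13 for Ptgs2, -0.16 to 0.38 for Ighm, -1.25 to 0.24 for Hbb-bs, -0.68 to 0.54 for Hba-a1, -0.090 to 0.17 for B2m, -0.15 to 0.081 for Sparc, -0.34 to 0.14 for Eno3 and -0.28 to 0.41 for Sbsn. They ran from -0.18 to 0.51 for Trp63, -0.0014 to 0.29 for Ager, -0.20 to 0.0025 for Vim, -0.17 to 0.10 for Tgfbi, -0.12 to 0.032 for Ctsb, -0.024 to 0.052 for Mcl1, -0.33 to 0.72 for Hmox1, -0.019 to 0.13 for Nfkbia and -0.15 to 0.012 for Padi4.

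With the median over members, exact p of list scores rose above 0.05 for interferon-stimulated genes (0.0571), hypoxia and glycolysis genes (0.171) and heat shock and immediate early genes (0.0571) and reached the smallest the design allows for T cell markers (0.0286) and X inactivation and Y-linked genes (0.0286). Differences turned sign for B and plasma cell markers (1), interferon gamma response and antigen presentation (0.0857), endothelial and angiogenesis genes (0.8), keratinocyte and skin genes (1), oxidative phosphorylation genes (0.886), p53 targets and apoptosis genes (0.371), NF-kB and inflammasome genes (0.743) and complement and coagulation genes (0.914), and with pseudocount 1 for dendritic cell markers (0.857). The causes were not tested. Depth limits genes such as Mpo and Elane, with at most 4 reads in any library.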

Other observations

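Genes outside the lists and the naming rule, chosen after their values were seen, are given here from the 517 DESeq2 calls. Selenop, a secreted selenoprotein, was at 47.6 ± 11.4 FPKM (SD, n = 4) in controls and 115.6 ± 47.0 (SD, n = 3) in ZQD, and the growth factor Igf1 at 0.181 ± 0.081 and 0.996 ± 0.476. Csf2ra, a subunit of the GM-CSF receptor, went from 16.3 ± 4.74 to 32.9 ± 4.63 FPKM, the cold-inducible RNA-binding protein Rbm3 from 93.9 ± 10.5 to 147.0 ± 14.1, and Ucp2, a mitochondrial carrier, from 18.4 ± 2.62 to 29.9 ± 1.86. Il1rl1, the interleukin 33 receptor, went from 57.4 ± 18.4 to 27.3 ± 4.04 FPKM and Ifit3b, a near-identical relative of Ifit3, from 14.3 ± 5.48 to 4.88 ± 1.10. None of these passed in limma (adjusted p 0.138 to 0.154) or edgeR (0.123 for each). Transcripts of the Y-linked genes Ddx3y and Eif2s3y were present in all 7 libraries, with 367 to 1049 reads, and Xist had 2 to 15 reads in each.

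The tests of immune cell share, tumour cell share and residual blood, and the split counts of limma genes and of lists, were chosen after the values they use had been seen. Among the 35 splits of the 7 libraries into 4 and 3, the real one had the most genes at an unadjusted p under 0.05 (1 of 35 splits, 2306 genes against at most 1803 in another). It also had the most DESeq2 calls (1 of 35, 517 against at most 324). That rank is the smallest p the design allows (1 in 35), which does not exclude chance for those counts. For genes past the adjusted limma threshold, 35 of 35 splits gave at least the real 0, the highest other giving 1. For gene lists past the threshold, 11 of 35 gave at least the real 16, the highest other giving 21, so the number of lists does not stand out from other splits.

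Interferon-stimulated genes were lower in ZQD for 23 of 23 members. After each library's trend with GC content and gene length was removed, the mean log2 fold change was -0.81 and the exact permutation p stayed at 0.0286, which argues against that trend as the whole cause. A smaller share of immune cells is argued against by macrophage and monocyte markers, whose mean log2 fold change was 0.47. Their score did not pass on its own (exact permutation p = 0.0857, with ZQD 1 below control 1), but the exact test at the 0.05 level rejected differences below -0.01, against the -0.80 of interferon-stimulated genes; this bears only on cells with those markers. A sequencing platform or batch that follows the groups stays open, since the labels do not assign either, as does an effect of the treatment, and the list call does not hold with an estimated correlation (adjusted p = 0.414).

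Hypoxia and glycolysis genes were lower in ZQD for 22 of 22 members. With libraries scaled without mitochondrially encoded genes, the mean log2 fold change was -0.48 in place of -0.53. This argues against the effect of the mitochondrial share on the scaling as the whole cause. Such rescaling shifts all genes nearly alike (median log2 fold change over all genes -0.0066 in place of -0.043). It does not bear on a difference in tissue or RNA that the share may reflect. After removal of the GC content and length trends it was -0.50 (camera adjusted p = 1.3e-07), with scores of 5.62 ± 0.23 (SD, n = 4) and 5.11 ± 0.31 (SD, n = 3) against 5.63 ± 0.23 and 5.10 ± 0.31 before. All ZQD libraries stayed below all controls and the mean nearly kept its size, which argues against that trend as the whole cause. The exact permutation p went from 0.0286 to 0.0571 because another of the 35 splits then gave a difference as large in size. A smaller part played by that trend therefore cannot be told apart from a group difference. Tumour size or oxygen supply may also differ with treatment and was not measured in these files.

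Neutrophil markers were higher in ZQD for 14 of 15 members. Blood left in the tissue may contribute. Without ZQD 2, the library richest in platelet and erythroid genes, the mean log2 fold change was 0.29 in place of 0.67, with a camera adjusted p of 0.00431. Over the 7 libraries the neutrophil score followed the platelet and erythroid score with Pearson r = 0.78 (exact permutation p = 0.0599) and Spearman rho = 0.39 (p = 0.396), the only relation computed, and r was -0.76 without ZQD 2 and control 1, so the relation rests on those samples. Blood and a group difference cannot be told apart with 1 such library.

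A further hypothesis was that ZQD tumours hold a smaller share of tumour cells, which would raise the markers of every host cell type. The gap between macrophage and endothelial scores differed between groups by 0.48 (exact permutation p = 0.114), which leaves this undecided. The result depends on the comparator: the endothelial mean log2 fold change was -0.015, with 0.20 without ZQD 1 and -0.18 without ZQD 2. Most other host cell lists had means above 0, such as adipocyte (0.91), lymphatic and pericyte (0.56) and fibroblast genes (0.31). Dendritic cell markers (0.014) and Schwann and nerve genes (-0.18) did not rise alike.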
